A study of Homo sapiens with 8 samples.

How the data were processed

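Gene expression was measured in U-87MG, an established human glioblastoma cell line, with biotin-labelled cDNA on Affymetrix-type whole-transcript arrays. The cells received either indole-3-carboxaldehyde (I3CA), an aldehyde derived from tryptophan, at 50 µM or the solvent DMSO, for 24 h. There were 8 arrays, 4 per group. The labels describe the 4 arrays of a group as biological replicates, without saying whether these were separate cultures. If they were not, the p-values measure only the spread between these samples.

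The values are log2 expression values that the authors deposited as 1 table, with 1 value per probe set (a group of probes for 1 transcript) and array. Per the submitters' processing notes the tools were oligo and RMA, without versions. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale. The array background correction was not repeated, since scanner files were not used here. Whether the 8 arrays were normalized together with other arrays is not given in the sources used here, nor is the genome build, so no coordinates are printed. The table held 13486 rows. The lowest mean of any row over the 8 arrays was 7.22. Whether the rows were filtered on brightness is not given in the sources used here, and the table has no measure of signal over background, so a row in it is not shown to be expressed. A fold change on such an array tends to understate the change in RNA, because probes carry background signal. Array scan date and slide were not given, so neither could be tested as a batch.

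Gene symbols came from GEO's platform annotation, which is from an older release. Of the rows, 11850 were paired with 1 gene symbol, 657 with several and 979 were not listed in that annotation. Symbols were kept as annotated, because the annotation gave no gene identifier through which to update them. AHRR was read as the AHR repressor, whose current symbol it is. RefSeq also lists AHRR as an older synonym of CYP1A1, and without an identifier that reading was not checked. Where several rows shared a gene, the row with the highest mean over all 8 arrays stood for it, which dropped 28 rows and left 11822 genes. Rows with several symbols or none were fitted separately.

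The comparison was I3CA against DMSO, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 8 arrays, no covariate). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes below come from this fit over all 11822 genes unless they are called adjusted over the list alone. Differences are given as I3CA minus DMSO on the log2 scale with the standard error (SE) of the fit. Before the data were examined, 26 gene lists were fixed, covering AHR (aryl hydrocarbon receptor) target genes and pathway components, tryptophan and aldehyde metabolism, stress, inflammation, cell cycle and matrix genes, glial markers, markers of other cell types, and ribosomal, histone and housekeeping genes. Of their 456 genes, 331 were measured, 12 of them matched by an older symbol. Each list was tested with camera in limma, which compares its members with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 26 lists. The mean of each array over the AHR target genes of xenobiotic metabolism and feedback was compared with an exact two-sided permutation test over all 70 assignments of the 8 arrays, whose smallest possible p is 0.029.

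The genes to be named were also fixed by rule. The rule took all measured AHR target genes of xenobiotic metabolism and feedback, together with AHR, ARNT, IL4I1, IDO1 and TDO2. It took the largest changes among genes past the threshold or, where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p in that direction. It also allowed up to 3 leading members of each list. IL4I1, IDO1 and CYP1A1 are not analysed here, since no row was paired with these symbols alone. Fewer than 5 genes passed in either direction.

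The fit was tested on simulated data with the means and residual spread of the 11822 genes and 200 changed genes in each of 10 sets. It recovered 53.1% of genes changed by 0.5, 92.5% of those changed by 1 and 98.2% of those changed by 1.5 on the log2 scale, with 6.02% false calls among all calls. These rates hold for sets with 200 changed genes. Where fewer genes change, the adjusted threshold is harder to reach and recovery is lower, so the rates do not carry over to the real data. A list of 20 genes shifted by 0.3 was recovered in 10 of 10 sets. None of 260 tests of unchanged lists was called; these simulated genes were independent of each other, which real genes are not.

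Whether equal replicate numbers pair the arrays was checked by correlating the deviations from the group means between same-numbered arrays. Across all genes the correlations were 0.04, 0.07, 0.05 and 0.32 for numbers 1 to 4, so the numbers were not taken as pairs in the main fit. This does not rule out a spread shared by replicate number in single genes, which the SEs of the main fit would then include. Alternatives tried were the replicate number as a block, leaving out dim genes, renormalizing, another variance prior, array weights, every row of the table, averaging the rows of a gene, a minimum fold of 1.5, an adjusted p under 0.01, camera with the correlation estimated from the data, fry (a set test that does not compare a list with other genes), and leaving out each array in turn. Chosen after seeing the data were leaving out both arrays numbered 4, leaving out the leading member of each list, and an exact permutation over arrays for each list other than the AHR target genes of xenobiotic metabolism and feedback. The number of arrays limits the precision: the median SE of a gene's log2 difference was 0.10, and the median half-width of its 95% confidence interval was 0.23.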

Results

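Expression profiles were collected from U-87MG glioblastoma cells treated for 24 h with 50 µM I3CA (4 arrays) or with the solvent DMSO (4 arrays). The comparison asked which genes respond to I3CA, listed by the submitters among established and presumed ligands of the aryl hydrocarbon receptor (AHR), a transcription factor activated by small molecules. The median log2 value of an array lay between 8.80 and 8.83 over the 13486 rows, and any 2 arrays correlated across genes at between 0.956 and 0.974. The first principal component held 24.8% of the variance and did not part the groups. It set both arrays numbered 4 apart, at scores of -15.3 for DMSO replicate 4 and -16.4 for I3CA replicate 4, while the other 6 arrays lay between -0.39 and 11.2.

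**Figure D1:**
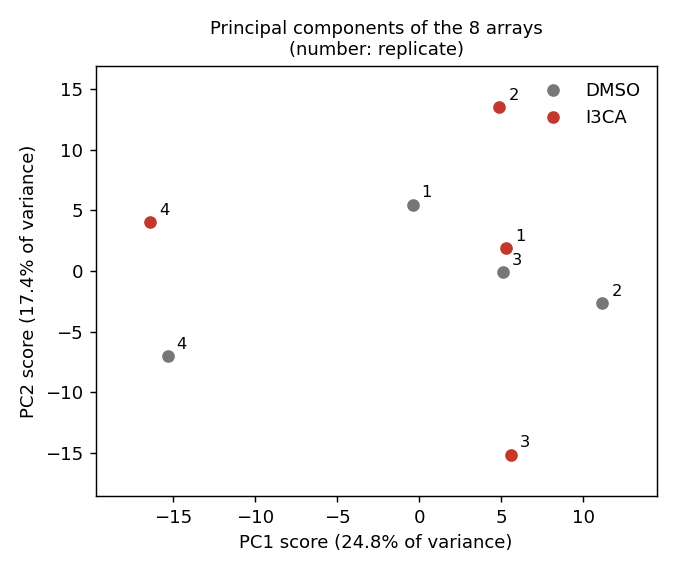
Scores of the 8 arrays on the first (24.8% of variance) and second (17.4%) principal components of the log2 values of 11822 genes, with DMSO arrays in grey, I3CA arrays in red and the replicate number beside each point. Both arrays numbered 4 lie at the left, at -15.3 and -16.4.

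SLC16A6 (probe set 16848073), which encodes a member of the monocarboxylate transporter family, rose 2.06-fold with I3CA. Its log2 expression was 9.94 ± 0.06 (SD, n = 4) with I3CA and 8.90 ± 0.05 (SD, n = 4) with DMSO, a difference of 1.04 ± 0.07 (SE; limma adjusted p = 0.00040). The 4 I3CA arrays lay between 9.87 and 10.0 and the 4 DMSO arrays between 8.85 and 8.96. SLC16A6 was the 1 gene of 11822 that passed the adjusted threshold in the limma fit, and 0 genes passed in the lower direction. At an unadjusted p under 0.05, limma counted 206 genes higher and 168 lower, together 374 or 3.16% of the genes, where chance alone gives about 591 on average and other splits of the 8 arrays gave 286 to 1053. Groups that did not overlap were seen in 227 genes, or 1.92%, against 2.86% by chance. SLC16A6 kept its call without both arrays numbered 4 (difference 1.06), as in the other fits tried.

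The other genes leading each direction did not pass the adjusted threshold, and their values are given without a call. On the higher side these were SCG5, encoding the neuroendocrine chaperone 7B2 (0.64 ± 0.11 SE), ZNF37A, a zinc finger gene (0.61 ± 0.13), ALDH1A3, which makes retinoic acid from retinaldehyde (0.52 ± 0.11), and ARID3B, a DNA-binding protein gene (0.45 ± 0.09). On the lower side these were DTNBP1 (-0.46 ± 0.09), OFD1, a centrosome and cilium gene (-0.44 ± 0.08), RBFOX1, a splicing factor gene (-0.39 ± 0.08), FKBP5, a co-chaperone of steroid receptors (-0.39 ± 0.08), and CRYBA4, a lens crystallin gene (-0.38 ± 0.08). In each of these 9 genes the 4 I3CA arrays lay all on one side of the 4 DMSO arrays, and the smallest adjusted p among them was 0.79.

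Of 12 AHR target genes of xenobiotic metabolism and feedback 7 were measured, and 5 of them had higher means with I3CA, with a median difference of 0.33 on the log2 scale. The list passed camera with the preset correlation (adjusted p = 0.0028) and did not pass with an estimated correlation (adjusted p = 0.41) or in the exact permutation test over arrays (p = 0.057). TIPARP, an ADP-ribosyltransferase that represses AHR, was 1.52-fold higher (0.60 ± 0.13 SE, 10.0 ± 0.25 SD with I3CA against 9.39 ± 0.16 SD with DMSO, n = 4 each). CYP1B1, a cytochrome P450 that oxidises xenobiotics and estrogens, was 1.49-fold higher (0.57 ± 0.15, 10.5 ± 0.21 against 9.89 ± 0.27). AHRR, the AHR repressor, was 1.26-fold higher (0.33 ± 0.11, 8.65 ± 0.21 against 8.32 ± 0.12), its row being named by a symbol that RefSeq also lists as a synonym of CYP1A1. In limma 0 of the 7 passed over all genes and 3 had an unadjusted p under 0.05, these same 3 genes. They passed when adjusted over the list alone, at adjusted p = 0.0060 for TIPARP, adjusted p = 0.0091 for CYP1B1 and adjusted p = 0.036 for AHRR. Over the AHR pathway components alone, to which AHRR also belongs, it did not pass (adjusted p = 0.086).

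The remaining members of that list did not pass either adjustment. ALDH3A1, an aldehyde dehydrogenase, differed by 0.54 ± 0.30, with a DMSO spread of 0.74 (SD) that came from DMSO replicate 2 at 6.76. ABCG2, a drug efflux pump, differed by 0.07 ± 0.13, NQO1, a quinone reductase, by -0.13 ± 0.09, and CYP1A2, another cytochrome P450, by -0.19 ± 0.23. Taking 1 mean per array over the 7 genes, I3CA arrays averaged 9.12 ± 0.13 (SD, n = 4) and DMSO arrays 8.86 ± 0.13 (SD, n = 4), a difference of 0.26, which is the difference given to the exact permutation test over the 70 assignments. Each I3CA array lay above the DMSO array of its number, where sign flips over numbered pairs gave their smallest possible p of 0.125. The camera call was also lost without TIPARP (median 0.20, adjusted p = 0.097). TIPARP was left out for having the smallest unadjusted p of the list in these data, so this check leans toward a weaker result. The call held without DMSO replicate 2, where the median was 0.17, and without genes under the median brightness, where it was 0.57. That cut dropped dimmer members such as AHRR and ALDH3A1, and the 0.57 is the difference of CYP1B1 itself.

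Of 30 other genes reported as AHR targets 20 were measured, and 16 of them had higher means with I3CA, with a median difference of 0.15. This second list passed camera with the preset correlation (adjusted p = 3.7e-06) and did not pass with an estimated correlation (adjusted p = 0.43) or in the exact permutation test over arrays (p = 0.14). Its means per array for replicates 1 to 4 were 10.0, 10.1, 10.0 and 9.65 with DMSO. With I3CA they were 10.2, 10.2, 10.3 and 9.92, each above the DMSO array of its number. Those last 2 tests were run without the replicate block, so they count a spread shared by replicate number as noise. SERPINB2, a plasminogen activator inhibitor, was 0.82 ± 0.19 higher on the log2 scale, EREG, an EGF receptor ligand, 0.41 ± 0.10 and STC2, a secreted glycoprotein, 0.48 ± 0.14. These 3 passed when adjusted over the list alone (adjusted p = 0.019, adjusted p = 0.019 and adjusted p = 0.046), while in limma 0 of the 20 passed over all genes and 5 had an unadjusted p under 0.05. STC2 did not pass over the integrated stress list alone (adjusted p = 0.16), to which it also belongs. IL1B, a proinflammatory cytokine, differed by 0.64 ± 0.37. Its arrays ran in the same order of replicate number in both groups. They ran from 10.0 in replicate 4 to 11.6 in replicate 2 with DMSO, and from 10.6 to 12.1 with I3CA. The SE of IL1B therefore includes a spread shared by replicate number. Of the 27 measured genes on the 2 AHR target lists, 14 are also on another list. The camera call held without DMSO replicate 4, where the median was 0.08.

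**Figure D2:**
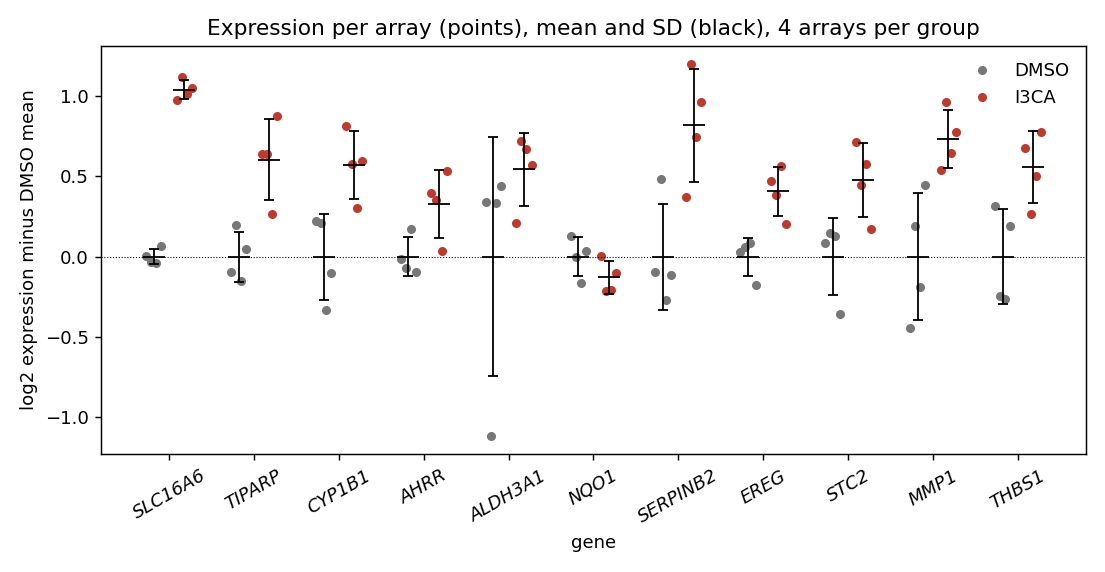
Log2 expression of 11 named genes on each array minus the gene's DMSO mean, with DMSO arrays in grey, I3CA arrays in red, and the mean and SD of 4 arrays in black. SLC16A6 is higher by 1.04 with little spread, TIPARP by 0.60 and CYP1B1 by 0.57, and NQO1 lies at -0.13.

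AHR and ARNT did not pass the threshold. AHR differed by 0.08 ± 0.09 and ARNT, its dimerisation partner, by -0.02 ± 0.11. Over 11 measured pathway components, which include TIPARP and AHRR, the median difference was 0.06 (camera adjusted p = 0.051, or adjusted p = 0.41 with an estimated correlation). This list passed without DMSO replicate 1 (adjusted p = 0.043), DMSO replicate 3 (adjusted p = 0.042), I3CA replicate 3 (adjusted p = 0.014) or I3CA replicate 4 (adjusted p = 0.024) and in 4 other camera settings, in a range from 0.014 to 0.49 over its alternatives. Without its leading member TIPARP, picked by its p in these data, the median was 0.04 (camera adjusted p = 0.32). Leaving out DMSO replicate 2 or 4 or I3CA replicate 1 or 2 gave a camera adjusted p of 0.060 to 0.30. Apart from TIPARP and AHRR, the smallest unadjusted p of a member in limma was 0.24 (NCOA3). The list, with TIPARP and AHRR in it, was the 1 of 26 at the smallest p that the exact permutation over arrays can give (p = 0.029, not adjusted over the lists). Genes of tryptophan catabolism and transport had a median difference of 0.03 over 12 members (adjusted p = 0.57), and TDO2, which opens the kynurenine pathway, differed by 0.03 ± 0.16. Among 20 measured enzymes of aldehyde and carbonyl metabolism the median was -0.07 (adjusted p = 0.56). ALDH1A3 alone of these passed when adjusted over the list alone (adjusted p = 0.015).

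Extracellular matrix and mesenchymal genes had a median difference of 0.06 over all 23 members, 17 of them above 0. The list passed camera with the preset correlation (adjusted p = 0.0028) and did not pass with an estimated correlation (adjusted p = 0.43), in the exact permutation test over arrays (p = 0.086) or without I3CA replicate 1 (median 0.01, adjusted p = 0.30). MMP1, an interstitial collagenase, was 0.73 ± 0.18 higher and passed when adjusted over the list alone (adjusted p = 0.045). THBS1, encoding thrombospondin 1, differed by 0.56 ± 0.16 (adjusted p = 0.054 over the list alone) and ITGB1, the integrin beta 1 gene, by 0.23 ± 0.10. In limma 0 of the 23 passed over all genes and 3 had an unadjusted p under 0.05. The camera call held without DMSO replicate 4, where the median was 0.03.

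The other stress and signalling lists did not pass the planned camera test. The NRF2 oxidative stress genes had a median of -0.04 (adjusted p = 0.29), led by NQO1, with GSR, the glutathione reductase gene, at -0.09 ± 0.09. The integrated stress and unfolded protein response had a median of 0.09 (adjusted p = 0.15), and its leading member STC2 is also on the second AHR list. Inflammatory mediators had a median of 0.06 (adjusted p = 0.29), led by LIF, an interleukin-6 family cytokine (0.45 ± 0.25), and IL1B. Interferon response genes had a median of -0.04 (adjusted p = 0.56), immediate early genes 0.02 (adjusted p = 0.29), heat shock proteins -0.04 (adjusted p = 0.56), p53 targets -0.03 (adjusted p = 0.43) and hypoxia and glycolysis genes 0.05 (adjusted p = 0.17). Cholesterol genes had a median of 0.00 (adjusted p = 0.56), led by INSIG1, a sterol sensor partner (0.28 ± 0.11). The S phase genes had a median of -0.02 (adjusted p = 0.58) and the G2 and mitosis genes -0.03 (adjusted p = 0.43). For TGF-beta and YAP targets the median was 0.04 and the mean -0.01 (adjusted p = 0.74). Without I3CA replicate 4 the integrated stress (median 0.15, adjusted p = 3.2e-05), inflammatory (median 0.17, adjusted p = 0.00021) and hypoxia lists (median 0.11, adjusted p = 0.0020) passed at the preset correlation. With all arrays and an estimated correlation, camera gave these 3 lists an adjusted p of 0.71, 0.72 and 0.71. The integrated stress list also passed without DMSO replicate 1 (adjusted p = 0.043), DMSO replicate 3 (adjusted p = 0.023) or genes under the median brightness (adjusted p = 0.027), the hypoxia list without DMSO replicate 3 (adjusted p = 0.023) and the inflammatory list without DMSO replicate 2 (adjusted p = 0.028). With the replicate block the integrated stress (camera adjusted p = 0.011) and inflammatory lists (adjusted p = 0.0023) passed. Both also passed without both arrays numbered 4 (camera adjusted p = 0.036 and adjusted p = 0.0098), while the hypoxia list did not. Leaving out I3CA replicate 4 alone keeps DMSO replicate 4 in the fit. In DMSO replicate 4 the mean of the integrated stress list was 9.04, against 9.55 to 9.65 in the other DMSO arrays. The mean of the inflammatory list was 8.83 in I3CA replicate 4, against 9.37 to 9.45 in the other I3CA arrays.

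Markers of cell identity and of RNA quality also stayed short of the threshold in that test. Glial and glioma stem cell markers had a median of 0.09 (adjusted p = 0.091), led by PROM1 (0.33 ± 0.12). The 3 measured endothelial markers had a median of 0.18 (adjusted p = 0.064), the 4 macrophage markers 0.07 (adjusted p = 0.58), the 8 neuron markers -0.05 (adjusted p = 0.70) and the 4 epithelial markers -0.01 (adjusted p = 0.70). Ribosomal protein genes had a median of -0.04 (adjusted p = 0.53), histone genes -0.10 (adjusted p = 0.18) and housekeeping genes -0.03 (adjusted p = 0.58), with HPRT1 at -0.07 ± 0.09. Glial markers passed without DMSO replicate 1 (median 0.14, adjusted p = 0.012) or I3CA replicate 3 (median 0.15, adjusted p = 0.044), endothelial markers without DMSO replicate 4 (adjusted p = 0.043) or I3CA replicate 3 (adjusted p = 0.014), and histone genes without DMSO replicate 2 (adjusted p = 0.032). In all, 3 of 26 lists passed camera with the preset correlation (7 at an unadjusted p under 0.05) and 0 with an estimated one (2 at an unadjusted p under 0.05). The 3 became 2 without I3CA replicate 1, 5 without both arrays numbered 4 or without DMSO replicate 2, and 7 without I3CA replicate 4. The count was 6 without DMSO replicate 1, DMSO replicate 3 or I3CA replicate 3. Of the 35 splits of the 8 arrays, 15, the real one included, called at least 3 lists. Most of these put both arrays numbered 4 on 1 side, unlike the real one. No split with 1 of them on each side called more than 3.

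**Figure D3:**
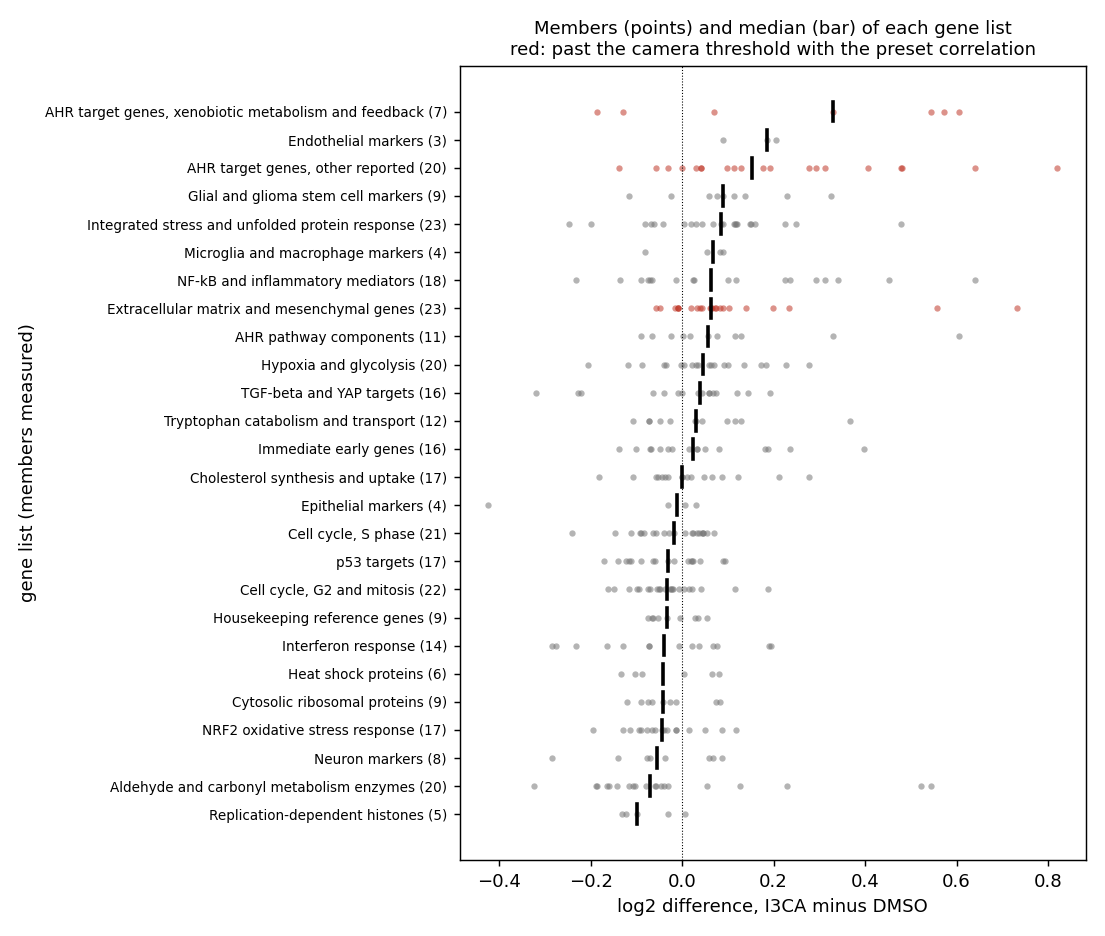
Log2 difference, I3CA minus DMSO, of each measured member (points) and the median (black bar) of 26 gene lists, with the number of measured members in brackets. Red marks the 3 lists past camera's threshold with the preset correlation, whose medians are 0.33, 0.15 and 0.06.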

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

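The test of the arrays numbered 4 on the AHR lists and that of splits with few genes at an unadjusted p under 0.05 were chosen after their results were seen, and the test of the strongest gene of each split after the number of genes per split was seen. In 14 of 234 groups of 4 arrays the highest or lowest array lay far from the other 3, where about 11.7 are expected by chance. In the DMSO group these were ALDH3A1 at 6.76 in replicate 2, with the other 3 arrays at 8.21 to 8.31, and HK2 at 10.02 in the same array. DDIT3 at 9.09 and DNAJB1 at 10.46 stood out in DMSO replicate 3, and MAP2 at 8.81 in DMSO replicate 1. DMSO replicate 4 was apart for ARNT at 10.26, STC2 at 9.61, HMGCS1 at 8.35, KDR at 8.48 and the mean of the integrated stress list at 9.04. In the I3CA group the values apart were RPS23 at 10.41 in replicate 3, the mean of the matrix list at 11.02 in replicate 1, the mean of the inflammatory list at 8.83 in replicate 4, and the first principal component at -16.4 in replicate 4.

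The first pattern is the upward shift of the AHR target lists in camera with the preset correlation, where, against a brightness-dependent shift between the groups, the median of their 27 members, 0.18, stood at percentile 100 of 10000 random lists matched on brightness, the highest of which reached 0.06. Against the 2 arrays numbered 4 as the cause, the second list kept its preset-correlation camera call (adjusted p = 6.2e-07, median 0.17) without them, a call that with all arrays was lost with an estimated correlation (adjusted p = 0.43) and in the exact permutation over arrays (p = 0.14). Chance is not excluded: 2 of the 35 splits of the 8 arrays, the real one included, gave a mean difference over these genes at least as large as the real 0.226. The highest other split gave 0.234. That split put both arrays numbered 4 on 1 side. Among splits with 1 of them on each side, as in the real groups, the real difference was the largest and the next was 0.138. No prediction was set for this part of the splits, so it does not exclude chance. With the replicate block both lists passed at the preset correlation (adjusted p = 0.0045 and adjusted p = 4.2e-10). Without the block neither passed with an estimated correlation (adjusted p = 0.41 and adjusted p = 0.43) or fry (adjusted p = 0.49). Chance and a response to I3CA both stay open.

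The second pattern is that SLC16A6 was the 1 gene past the threshold. A single array does not account for it, since over the 8 fits that left out 1 array its highest adjusted p was 0.0046. Signal shared with neighbouring genes is argued against by a median difference of -0.015 over the 5 nearest measured genes on each side, none at an unadjusted p under 0.05. A count of at least 1 gene was reached in 3 of the 35 splits, with 1 in the highest other, and that count does not exclude chance. By strength, only the real split of the 35 had a gene with a moderated t (limma's difference over its SE) as large as 14.3. The highest other split reached 9.39, with a limma adjusted p of 0.024. A share of 1 in 35 is the smallest that these splits can give, and this measure was chosen after the counts were seen. It argues against chance but does not exclude it, and a response of SLC16A6 to I3CA stays a hypothesis.

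The third pattern is that 3.16% of genes had an unadjusted p under 0.05, below the 5% that chance gives on average. Chance is not excluded, since 3 of the 35 splits had no more such genes than the real 374 and the lowest other had 286. If the 2 arrays numbered 4 inflated the spread within groups, leaving them out should have brought the share to 5% or more. It was 3.17%, and another choice of 1 array per group reached 4.91%. The splits point the other way. Those with 1 array numbered 4 on each side, as in the real groups, gave 286 to 762 such genes. Those with both on 1 side gave 464 to 1053. These 2 arrays as a cause therefore stay open. With the replicate block the share was 4.71%, near the 5% of chance, so a spread shared by replicate number stays open, and no biological explanation was tested.

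For the number of lists past camera, 15 of the 35 splits called at least the real 3 and the highest other split called 7. Most of these put both arrays numbered 4 on 1 side, unlike the real one. Among splits with 1 of them on each side the highest count was the real 3. Other such splits also reached 3, so chance is not excluded. Splits with both arrays numbered 4 on 1 side gave up to 1053 genes at an unadjusted p under 0.05, against the real 374, which points to a structure of the samples that the groups do not follow; with the replicate block the number of lists was 5.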

How the results depend on the processing

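Chosen after seeing the data were leaving out both arrays numbered 4, leaving out the leading member of each list and the exact permutation over arrays for every list except the xenobiotic AHR list, for which it was planned. The count of 1 gene past the threshold was the same in all 20 alternatives, and that gene was SLC16A6 in each fit. Its adjusted p ranged from 2.8e-05 to 0.030, the latter with the replicate block. The number of lists past camera was 3. It was 5 with the replicate block, 5 without genes under the median brightness, 5 without both arrays numbered 4, 0 with an estimated correlation and 0 with fry (2 each at an unadjusted p under 0.05), and 2 to 7 when 1 array was left out. All 3 lists lost their call, at medians of 0.33, 0.15 and 0.0627, with an estimated correlation (adjusted p = 0.41, 0.43 and 0.43) and with fry (adjusted p = 0.49 for each). The correlations estimated for them were 0.11, 0.29 and 0.12, against the preset 0.01. These 3 lists also missed 0.05 in the exact permutation over arrays, with mean differences of 0.258, 0.216 and 0.107 (p = 0.057, p = 0.14 and p = 0.086). The xenobiotic AHR list also lost its call without its leading member TIPARP (0.20). Leading members were picked by their p in these data, so leaving them out leans toward weaker lists. The matrix list ranged from 0.0122 to 0.0874 with 1 array left out, and lost its call without I3CA replicate 1. In the other alternatives these 3 lists kept their call, and 26 values of other lists, of 571 list values in all, passed. These were 9 for AHR pathway components, 6 for the integrated stress list, 4 for inflammatory mediators, 2 each for hypoxia, glial and endothelial genes and 1 for histones. The 9 include the exact permutation over arrays (p = 0.029), which unlike the camera values is not adjusted over the lists. What made these other lists pass was not tested. The AHR group mean difference of 0.26 did not pass in any alternative (0.20 to 0.32 with 1 array left out); 2 of these could not pass, since sign flips over numbered pairs cannot go below 0.125 and 3 arrays against 3 cannot go below 0.1, the p reached without both arrays numbered 4. The block changed no other called result: it added the integrated stress (adjusted p = 0.011) and inflammatory lists (adjusted p = 0.0023). In deviations from the group means, 2 of the 8 arrays correlated best with their own number in the other group. The block took the genes at an unadjusted p under 0.05 from 374 to 557. Of 1543 values of 89 named genes under alternatives, 0 moved across the threshold, and 22 that were never called changed sign, as did 31 list values. For the exact permutation over arrays the sign of a list's mean difference was set against that of its main median. TGF-beta and YAP targets (median 0.04, mean -0.01) therefore count as a change there without any change in the values. The table carries no measure of signal over background, so how background limits these results was not measured.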

Other observations

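The 3 lists in this part were chosen after the leading genes were seen, and their tests were written before they were run. The hypothesis that other members of the SLC16 transporter family are higher together with SLC16A6 found no shift past the threshold: over 5 measured members the median difference was -0.01 (camera p of 0.82), with SLC16A1, the widely expressed lactate transporter MCT1, at 0.01 ± 0.09 and SLC16A3, MCT4, at -0.01 ± 0.13. The hypothesis that glucocorticoid-responsive genes are lower together with FKBP5 found none either, with a median of 0.00 over 15 other genes (camera p of 0.63), TSC22D3 at 0.07 ± 0.10 and PER1 at -0.03 ± 0.17. For EGF family ligands other than EREG the median over 6 genes was 0.05 (camera p of 0.21). Of these, TGFA and HBEGF, which bind the EGF receptor, were at -0.02 ± 0.11 and -0.11 ± 0.11. The other 4 are neuregulins, which bind ERBB4 and, for some of them, ERBB3, with NRG1 at 0.27 ± 0.15. These p-values are unadjusted, and with the number of arrays at hand they do not show that the groups are equal.

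Among the 1636 rows with several gene symbols or none, 0 passed the adjusted threshold in limma and 55 had an unadjusted p under 0.05.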
